A study of Homo sapiens with 6 samples.

How the data were processed

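RNA was profiled in PLC/PRF/5 hepatocellular carcinoma cells on 6 single-colour Affymetrix expression arrays. Per the labels' protocols, cells grown in DMEM were transfected with siRNA duplexes using a lipid reagent, harvested in TRIzol, and their total RNA was cleaned on RNeasy columns. From 5 micrograms of RNA, cDNA was made in a single cycle and transcribed in vitro into biotin-labelled cRNA, per the labels. The deposited values are RMA probe set intensities, per the submitters' processing notes, which name no version. RMA corrects background, normalises between arrays and summarises the probes of a set, so these steps were taken by the authors before deposit. Whether the background model used GC content is not given in the sources used here. The values are on a linear scale, running from about 1.90 to 8976, and were turned into log2 here, a step that the design had allowed for. Quantile-type normalisation assumes that most genes do not change, and it can compress global shifts. RMA also draws the log2 values of dim probe sets together, so fold changes of dim genes can be understated. No detection calls were used, and 54.9% of genes had a mean under 5.

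Each array's group and replicate number came from its title, and all 6 columns of the table were used. The only comparison was siWT minus siGL, 3 arrays against 3. The highest number of identical values between any pair of arrays was 222 of 54675, so no array was a copy of another.

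Probe sets were named with the platform's annotation table, updated by Entrez identifier through RefSeq names of the GRCh38.p14 assembly, from which no coordinates were taken. Of the 54675 rows, 62 were control probe sets. The annotation listed 42898 probe sets, 41091 with 1 gene symbol and 1801 with several, and 11721 others were not listed and stay unnamed here. An identifier match was found for 41037 of those with 1 symbol, and 0 symbols changed. A gene was represented by the probe set with the highest mean over all arrays among those with exactly 1 symbol, which gave 19775 genes. Of the 10523 genes with several probe sets, 756 had at least 2 that passed the threshold, and in 30 of these the probe sets went in opposite directions.

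Differences were tested on log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no filter on dim genes and no covariate. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. SE is the moderated standard error, and SD is over 3 arrays. The same test was run over the 54613 probe sets other than controls. The 22 gene lists held 564 distinct genes, of which 518 were measured and 46 were not analysed here. Lists were tested with camera against the other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 22 lists. Camera with an estimated correlation and fry were run beside it. An estimated correlation also leaves camera with the residual degrees of freedom of the fit, far fewer than with a preset one. Control probe sets for ACTB and GAPDH were compared between groups with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 against 3.

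The rule for named genes was fixed before the data were examined. It took WT1, the 12 genes that rose most and the 12 that fell most by fold among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 6, and up to 4 members of each list with the strongest change among those past the threshold. Where no member of a list passed, the member with the smallest p was given as values only. CFLAR and FADD were always given, and 1 further gene of the rule is not reported here. Other list members named in the text were chosen after their values were seen.

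The scripts were tested on simulated data with the variances of these arrays. With 200 of the 19775 genes changed, limma recovered 17.9% of those changed by 1.25-fold, 58.2% at 1.5-fold and 93.9% at 2-fold. Far more genes passed in the real comparison, 16.3% of those tested, so these recovery rates need not apply to it. Of 119 calls 6 were false, and 0 had the wrong sign. In the list test, a simulated list with a shift was called and 0 of 21 unchanged lists were. Simulated genes were drawn independently of one another, so this does not show how often camera calls unchanged lists of correlated genes.

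Alternatives chosen before the data were examined were the replicate number as a block, each array left out in turn, quantile, cyclic loess and housekeeping normalisation, a trended and robust prior, array weights, filters on dim genes, other rules for the probe set of a gene, a plain t statistic without shared variance, a test against a fold of 1.2, and other list tests. Housekeeping centring used 14 measured genes of 18 listed. After the data were examined, the list counts and camera with an estimated correlation were also run without siGL replicate 2. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.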

Results

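Gene expression was measured in PLC/PRF/5, an established human hepatocellular carcinoma cell line, after transfection with small interfering RNAs. WT1 encodes a zinc finger transcription factor, and the series was made to find how silencing it affects the transcriptome of these liver cancer cells. The 6 arrays fell into 2 groups of 3. The siGL group received a control duplex and the siWT group received 2 duplexes directed at WT1, in exons 7 and 10. Each array gave a normalised intensity for 54675 probe sets, and all values below are on the log2 scale unless an intensity or a fold is named. The number of arrays limits the precision. The labels say that transfections were done in triplicate and nothing more about separate cultures, so p-values measure the spread between these samples, which may be technical.

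The arrays had similar distributions, with median intensities between 8.23 and 8.67. Within a group the lowest correlation between arrays was 0.996, across probe sets, which are not independent replicates. One control array, siGL replicate 2, stood apart in its control probe sets for 18S ribosomal RNA. Its intensity was 842.6 on the 5' control probe set, against 52.6 to 90.4 on the other 5 arrays, and 624.2 on the 3' control probe set, against 56.3 to 88.3. Its ACTB 3' minus 5' log2 difference, which grows as messages lose their 5' ends, was 0.94, against 0.36 to 0.65 elsewhere. Between the groups this ACTB difference was 0.56 ± 0.33 in siGL and 0.56 ± 0.08 in siWT (SD, n = 3 each; two-sided exact permutation p = 1, where the smallest possible p is 0.1). These equal means rest on siGL replicate 2. The other siGL arrays had 0.36 and 0.37, below all 3 siWT arrays (0.49 to 0.65), and without siGL replicate 2 the ACTB difference was 0.20 higher in siWT, so this sign of RNA quality moves with the groups. The GAPDH 3' minus 5' difference went the other way, shifted by -0.05 in siWT with the smallest possible exact permutation p of 0.1, and by -0.03 without siGL replicate 2. The GAPDH 3' minus middle difference moved with ACTB instead, 0.02 higher in siWT without that array and with no overlap between the groups. The control probe sets for 28S ribosomal RNA moved further once siGL replicate 2 was left out, 0.67 higher in siWT on the 5' probe set and 0.75 on the middle one, in both cases with no overlap between the groups, while the dim 3' one had a difference of -0.27 with overlap. Counts of changed genes are therefore given with and without siGL replicate 2.

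**Figure D1:**
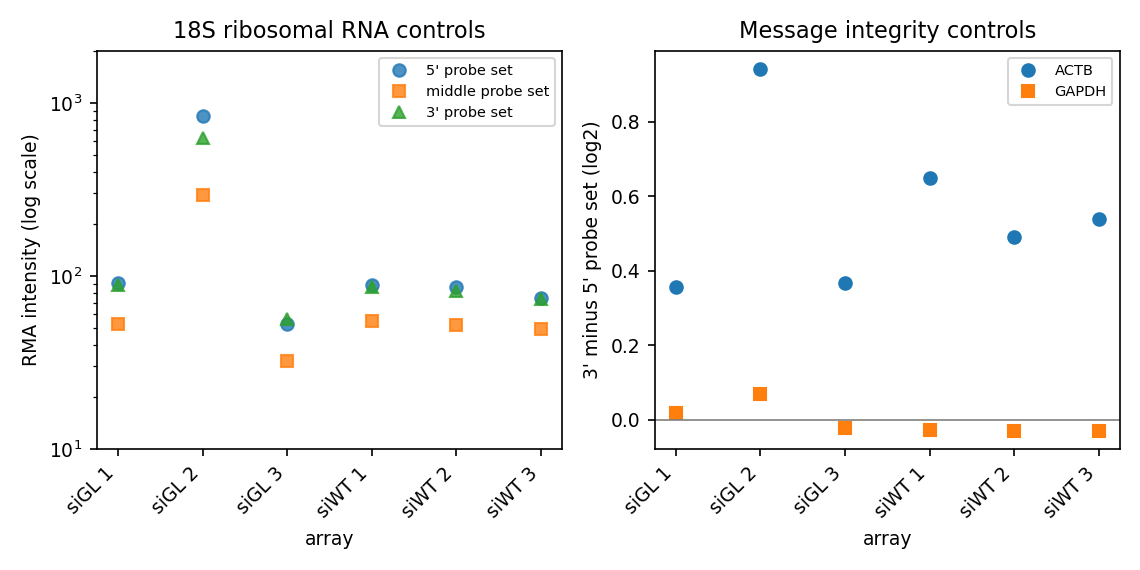
Left, intensity (log axis) of the 5', middle and 3' control probe sets for 18S ribosomal RNA on each of the 6 arrays; right, the 3' minus 5' log2 difference of the ACTB and GAPDH controls. Each point is 1 array, and siGL 2 lies above the other 5 arrays for the ribosomal RNA and ACTB controls (842.6 on the 5' probe set; 0.94 for ACTB).

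The silenced gene was measured first in every sample. WT1 (probe set 206067_s_at) was 5.74, 5.83 and 5.81 in the siGL arrays and 4.72, 4.46 and 4.49 in the siWT arrays. The mean fell from 5.79 ± 0.04 to 4.55 ± 0.14 (SD, n = 3 each), a log2 change of -1.24 (SE 0.08; limma adjusted p = 8.92e-05) that left 42.4% of the control intensity. The second WT1 probe set, 216953_s_at, was dim and fell from 3.47 ± 0.11 to 2.82 ± 0.26, a log2 change of -0.65 (limma adjusted p = 0.0152). Every siWT array lay below every siGL array on both probe sets.

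**Figure D2:**
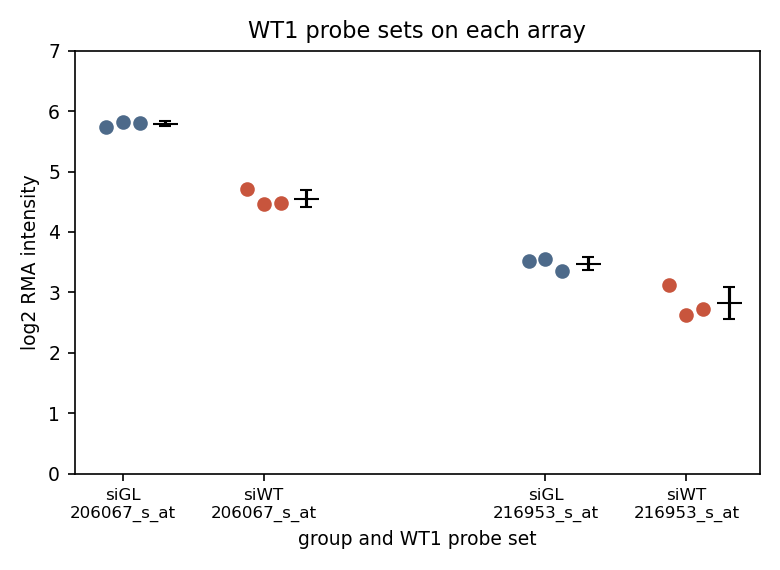
Log2 RMA intensity of the 2 WT1 probe sets on each array, siGL in blue and siWT in red, with the group mean and SD (n = 3) as a black bar beside the points. The siWT arrays lie below the siGL arrays on both probe sets, with means of 4.55 against 5.79 on 206067_s_at and 2.82 against 3.47 on 216953_s_at.

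With WT1 silenced, gene lists for liver plasma proteins and hepatocyte transcription factors were higher, and lists for G2 and mitosis, hypoxia and glycolysis, and EGFR ligands and ERBB signalling were lower, in a set test with a preset correlation. None of these 5 calls held when the correlation was estimated (camera adjusted p from 0.231 to 0.334), a setting that also lowers the test's degrees of freedom. Of 19775 genes tested, 3219 differed between the groups in limma at an adjusted p under 0.05, with 1640 higher and 1579 lower in siWT. Most changes were small, as 686 of these genes changed by at least 1.5-fold (289 higher, 397 lower) and 125 by at least 2-fold (45 higher, 80 lower). All 3219 genes had siWT values that did not overlap the siGL values. Over all genes tested, 35.4% had groups that did not overlap, against the 10% that chance gives with 3 against 3. Without siGL replicate 2, 2804 genes passed, 1486 higher and 1318 lower. The count fell further without siWT replicate 1, 2 or 3 (1896, 2102 and 1854 genes) and under housekeeping centring (1904 genes). The ACTB and 28S controls given above moved with the same groups, without siGL replicate 2.

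Among genes with a mean of at least 6 in the higher group, SULT2A1, a hepatic sulfotransferase of steroids and bile acids, rose most. Its level went from a dim 4.32 ± 0.35 in siGL to 6.33 ± 0.06 in siWT (SD, n = 3 each), 4.04-fold higher (log2 change 2.01, SE 0.15; limma adjusted p = 1.50e-04; probe set 206292_s_at). STMN3, of the stathmin family of microtubule regulators, rose 3.85-fold, and APOH, a phospholipid-binding plasma protein, rose 3.75-fold (log2 changes 1.94, SE 0.11, and 1.91, SE 0.07). CDC42SE2, a small effector of the GTPase CDC42, rose 3.25-fold, and SAMHD1, which hydrolyses deoxynucleoside triphosphates, rose 3.06-fold. CHGB, a secretory granule protein, was 3.03-fold higher. SLC30A10, a manganese exporter, was 2.76-fold higher and TM4SF4 2.72-fold higher. G6PC1, the catalytic subunit of hepatic glucose-6-phosphatase, rose 2.75-fold with a wide error (log2 change 1.46, SE 0.23), since siGL replicate 2 had an intensity of 109 against 197.6 and 215.3 in the other siGL arrays, and it lost its call with a plain t statistic (adjusted p = 0.0680). SLC7A11, the cystine and glutamate antiporter, rose 2.64-fold, PAQR9 2.63-fold and ARL6IP5 2.62-fold. A second, dim probe set of PAQR9 went the other way (log2 change -0.38; limma adjusted p = 0.0339 over probe sets). With all probe sets of a gene averaged, the log2 changes of STMN3, APOH and PAQR9 were 1.12, 1.09 and 0.51, still past the threshold.

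CGA, the alpha subunit shared by the glycoprotein hormones, fell most. It went from 9.13 ± 0.08 in siGL to 7.06 ± 0.02 in siWT (SD, n = 3 each), 4.20-fold lower (log2 change -2.07, SE 0.07; limma adjusted p = 1.02e-05; probe set 204637_at). IER3, an immediate early gene, was 3.91-fold lower and GJA1, a gap junction connexin, was 3.69-fold lower. CDCA3, which acts at entry into mitosis, was 3.40-fold lower on one probe set and had a log2 change of -1.64 on the other. ABITRAM was 3.31-fold lower, TMEM161B 3.16-fold lower and C17orf58 3.16-fold lower. CEMIP2, a cell surface protein of hyaluronan breakdown, was 3.14-fold lower. The noncoding transcript CNN3-DT was 3.10-fold lower and TLCD5 3.09-fold lower. ID1, an inhibitor of basic helix-loop-helix factors and a target of BMP signalling, went from 11.67 ± 0.19 to 10.06 ± 0.08, 3.05-fold lower. TCIM was 2.93-fold lower. Log2 changes of these 12 genes ran from -2.07 to -1.55, with limma adjusted p of at most 6.32e-05. Averaged over all their probe sets, CGA, TMEM161B and CNN3-DT had smaller log2 changes of -1.03, -0.78 and -1.03 that still passed.

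**Figure D3:**
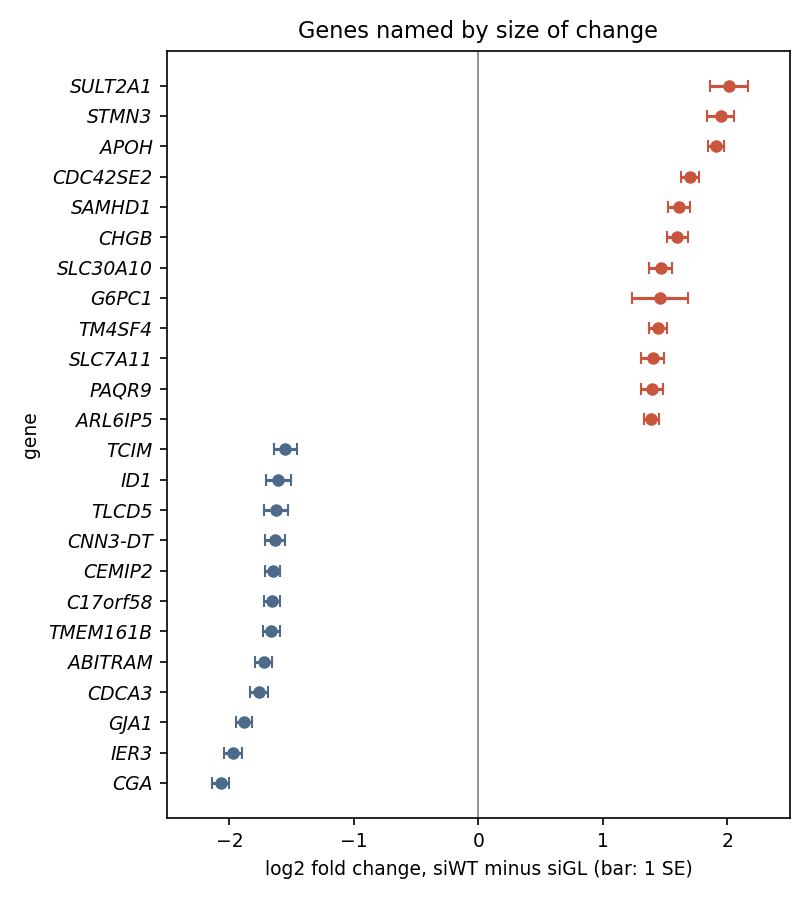
Log2 fold change, siWT minus siGL, of the 12 genes that rose most (red) and the 12 that fell most (blue) among genes past the threshold with a mean of at least 6 in the higher group; bars are 1 SE from limma (n = 3 per group). Changes run from -2.07 for CGA to 2.01 for SULT2A1, and G6PC1 has the widest bar (SE 0.23).

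The 22 gene lists below were fixed before the data were examined. Of 29 measured genes in the list for plasma proteins secreted by the liver, 18 rose, 1 fell and 10 did not pass. APOH rose 3.75-fold, transthyretin (TTR) and albumin (ALB) each rose 2.35-fold (log2 changes 1.23, SE 0.07 for both), and TTPA rose 2.11-fold. TTPA, the alpha-tocopherol transfer protein, acts inside hepatocytes and is not itself secreted, although the list holds it. TTR was a dim gene, at 4.03 ± 0.06 in siGL and 5.27 ± 0.04 in siWT. The member that fell was APOM (log2 change -0.27). When adjusted over the list alone, 19 rose and 1 fell, and without siGL replicate 2 the counts were 16 and 1. The list was higher as a set in camera (adjusted p = 3.21e-12), with an adjusted p = 0.231 with an estimated correlation.

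Of 15 measured hepatocyte transcription factor genes, 7 rose, 2 fell and 6 did not pass. ONECUT2 rose 1.84-fold and ONECUT1 1.43-fold, both hepatocyte nuclear factors of the cut homeobox class. TBX3 was 1.56-fold lower and CEBPB 1.53-fold lower, and the latter encodes a factor of the acute phase response. With p-values adjusted over the list alone, 8 rose and 2 fell, and without siGL replicate 2 the counts were 6 and 2. The set passed camera (adjusted p = 0.0131) and had an adjusted p = 0.295 with an estimated correlation. Its call ended when dim genes were left out, with an adjusted p of 0.0868 at a mean of at least 5 and 0.127 above the median gene. The members' own mean did not shrink, with a mean log2 change of 0.16 ± 0.40 over all 15 members (SD over members), 0.20 ± 0.44 over the 12 with a mean of at least 5 and 0.17 ± 0.41 over the 14 above the median gene. The mean log2 change of the other genes rose, from -0.02 to 0.02 at a mean of at least 5 and 0.01 above the median gene. Fewer members were also set against other genes that spread more widely (SD 0.25 over all other genes, and 0.30 under either filter). Camera itself works from moderated t statistics rather than log2 changes. The members' mean t was 1.96 over all genes, 2.82 at a mean of at least 5 and 2.33 above the median gene. The SD of t over the other genes was 3.08, 4.74 and 4.56 in the same order.

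Liver metabolic enzymes did not pass as a set (camera adjusted p = 0.0688), although 6 of 31 rose and 1 fell. ADH1A, an alcohol dehydrogenase, rose from a dim 2.91 ± 0.12 to 5.14 ± 0.32 (SD, n = 3 each; limma adjusted p = 9.03e-05). No fold is given for it, since its siGL intensities (6.9 to 8.1) lay below the median intensity of their arrays. BAAT, which conjugates bile acids to amino acids, rose 2.21-fold, and SULT2A1 and G6PC1 also belong to this list. Of the 31 enzymes, 9 had a mean of at least 5. Adjusted over the list alone, the counts were again 6 and 1, and without siGL replicate 2 they were 7 and 0, with camera then past the threshold under the preset correlation (adjusted p = 0.0307) but not under an estimated one (adjusted p = 0.359, and 0.295 over all arrays). Fetal liver, progenitor and hepatocellular carcinoma markers went both ways, with 4 of 20 higher and 5 lower (camera adjusted p = 0.424). The imprinted gene PEG10 rose 1.90-fold and the oncofetal proteoglycan gene GPC3 1.65-fold, while GOLM1, a Golgi membrane protein, was 1.81-fold lower and SPP1, osteopontin, 1.58-fold lower. When adjusted over the list alone, 5 rose and 7 fell, and without siGL replicate 2 the counts were 4 and 5.

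**Figure D4:**
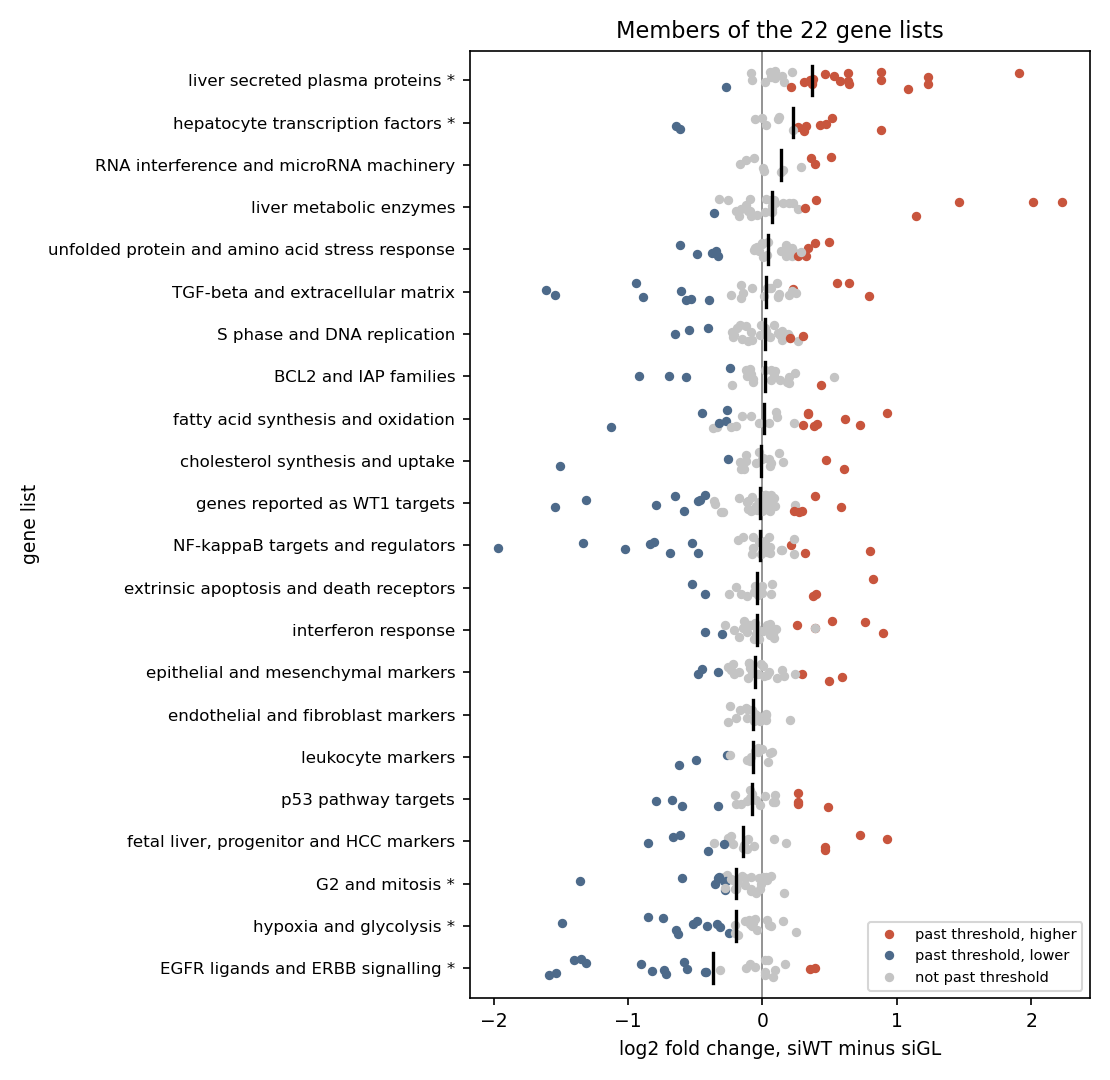
Log2 fold change, siWT minus siGL, of each measured member (points) of the 22 gene lists, with the list's median as a black line; red and blue points passed the threshold and grey points did not. Asterisks mark the 5 lists past camera with its preset correlation, none of which passed with an estimated one. The lists run from liver secreted plasma proteins (18 of 29 higher) at the top to EGFR ligands and ERBB signalling (13 of 26 lower) at the bottom.

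In the list of EGFR ligands and ERBB signalling, 13 of 26 genes fell and 2 rose. The members that fell included SPRY4, a feedback inhibitor of the pathway (3.01-fold lower), the immediate early transcription factor EGR1 (2.91-fold lower), and the ETS factors ETV5 (2.65-fold lower) and ETV4 (2.56-fold lower), which are known targets of ERK signalling. The ligand EREG fell too (log2 change -0.58). The members that rose were the receptor EGFR (log2 change 0.39) and PHLDA1 (0.35). The ligands TGFA, HBEGF, BTC, EGF and NRG1 and the receptors ERBB2, ERBB3 and ERBB4 did not pass, with log2 changes of -0.32, -0.06, 0.09, 0.02, 0.08, 0.04, 0.02 and 0.02. Of 27 listed genes 26 were measured, and no value is given here for the ligand AREG, which the list also holds. With p-values adjusted over the list alone, the counts were the same, and without siGL replicate 2 they were 13 lower and 1 higher. The set was lower in camera (adjusted p = 1.97e-04), with an adjusted p = 0.295 with an estimated correlation.

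Genes reported as WT1 targets elsewhere went both ways, with 5 of 44 higher and 8 lower (camera adjusted p = 0.418). CCN2, a matricellular protein, was 2.92-fold lower, the ERK phosphatase DUSP6 2.48-fold lower, the AP-1 subunit JUNB 1.73-fold lower, and cyclin E1 (CCNE1) 1.57-fold lower. Adjusted over the list alone, 6 rose and 9 fell, and without siGL replicate 2 the counts were 4 and 7. Among NF-kappaB targets and regulators, 8 of 28 fell and 3 rose. IER3 was 3.91-fold lower and the chemokine genes CCL20, CXCL5 and CXCL1 were 2.52-fold, 2.04-fold and 1.79-fold lower, while the other 17 members did not pass and the set did not pass camera (adjusted p = 0.179). The counts were the same adjusted over the list alone, and 8 lower and 2 higher without siGL replicate 2. In the list for TGF-beta and extracellular matrix, 8 of 28 fell and 4 rose. ID1 was 3.05-fold lower, CCN2 2.92-fold lower, CCN1 1.92-fold lower and SMAD3, a signal transducer of TGF-beta receptors, 1.85-fold lower. This list's median was 0.02 while its mean was -0.16 and camera pointed down (adjusted p = 0.459). When adjusted over the list alone, 5 rose and 8 fell, and without siGL replicate 2 the counts were 5 and 9.

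In the list for G2 and mitosis, 8 of 33 genes fell, 0 rose and 25 did not pass in limma (17 and 0 at an unadjusted p under 0.05). The set was lower in camera with the preset correlation (adjusted p = 1.66e-04) but not with an estimated one (adjusted p = 0.334). AURKA, a mitotic spindle kinase, had by far the strongest change (2.56-fold lower, from 11.16 ± 0.05 to 9.81 ± 0.01; SD, n = 3 each), and its second bright probe set had a log2 change of -1.34. HMMR, a spindle-associated hyaluronan receptor, was 1.51-fold lower. CENPA, the centromeric histone, and the kinase AURKB were 1.28-fold and 1.26-fold lower, and both lost their calls in 5 of the 6 fits that left out 1 array and with a plain t statistic. Both calls were also lost with a replicate block (limma adjusted p = 0.0662 and 0.0539). AURKB also lost its call with its probe sets averaged (log2 change -0.15; adjusted p = 0.249), and CENPA with the most variable probe set of each gene (adjusted p = 0.0511). With p-values adjusted over the list alone, 10 fell and 0 rose, without siGL replicate 2 the counts were 7 and 0, and with genes of a mean under 5 left out they were 16 and 0. Genes of S phase and DNA replication did not move as a set (camera adjusted p = 0.917), with 2 of 31 higher, 3 lower, a median of 0.02 and a mean of -0.03. CCNE1 was 1.57-fold lower, the replication factor CDC45 1.46-fold lower and the ribonucleotide reductase subunit RRM2 1.32-fold lower, while the primase subunit PRIM1 rose 1.23-fold, a call lost under housekeeping centring (adjusted p = 0.0676). Adjusted over the list alone, 5 rose and 5 fell, without siGL replicate 2 the counts were 2 and 3, and with dim genes left out 7 of 30 rose and 7 fell.

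CFLAR and FADD, of the extrinsic apoptosis pathway, were chosen in advance whatever their values. CFLAR, an inhibitor of caspase-8 activation, was 1.44-fold lower on its brightest probe set, 209939_x_at (log2 change -0.52, SE 0.06; limma adjusted p = 0.00113). Its next brightest probe set, 210563_x_at, also fell (-0.59), the other 12 probe sets did not pass, and the mean of all its probe sets had a change of -0.03 that did not pass. FADD, the adaptor of death receptors, had a log2 change of 0.06 (SE 0.06; limma adjusted p = 0.550). Of 17 genes of extrinsic apoptosis and death receptors, 3 rose and 2 fell (camera adjusted p = 0.896). The death ligand TNFSF10 rose 1.77-fold and the BH3-only protein BID 1.32-fold, and TNFRSF1A was 1.35-fold lower. The counts were the same adjusted over the list alone and without siGL replicate 2. In the BCL2 and IAP families, 4 of 23 fell and 1 rose (camera adjusted p = 0.917, with a median of 0.02 and a mean of -0.04). The anti-apoptotic BCL2L2 was 1.89-fold lower and BCL2L1 1.48-fold lower, the pro-apoptotic PMAIP1 was 1.62-fold lower, and the pro-apoptotic BCL2L11 rose 1.35-fold. BCL2L1 and BCL2L11 lost their calls with the most variable probe set of each gene (log2 changes -0.38 and 0.50; adjusted p = 0.237 and 0.0532). The counts were the same adjusted over the list alone, and 3 lower and 1 higher without siGL replicate 2. The balance depended on the filter, as 5 rose and 5 fell of the 20 members with a mean of at least 5 when dim genes were left out, and 6 rose and 5 fell at an unadjusted p under 0.05. Of 22 p53 pathway targets, 4 rose and 4 fell (camera adjusted p = 0.642). ZMAT3, DDB2 and RRM2B were 1.73-fold, 1.59-fold and 1.52-fold lower, SESN1 rose 1.40-fold (its call was lost with a plain t statistic, adjusted p = 0.0712), and the counts were the same adjusted over the list alone and 3 and 3 without siGL replicate 2.

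Among genes of hypoxia and glycolysis, 11 of 26 fell, 0 rose and 15 did not pass in limma (14 and 1 at an unadjusted p under 0.05). As a set they were lower in camera with the preset correlation (adjusted p = 5.94e-05) and did not pass with an estimated one (adjusted p = 0.238). ANKRD37, a hypoxia-induced gene, was 2.82-fold lower, the prolyl hydroxylase EGLN3 1.81-fold lower from a dim level (its call was lost with a plain t statistic, adjusted p = 0.0813), the glycolytic regulator PFKFB3 1.67-fold lower and adrenomedullin (ADM) 1.56-fold lower. The glucose transporters SLC2A3 and SLC2A1 and the glycolytic enzymes HK1, HK2, PKM, ALDOA and ALDOC also fell. The glycolytic genes LDHA, PGK1, ENO1 and GAPDH did not pass, with log2 changes of -0.08, -0.06, -0.04 and -0.07, and neither did VEGFA (0.05). When adjusted over the list alone, 14 fell and 1 rose, without siGL replicate 2 the counts were 10 and 1, and with dim genes left out 12 of 23 fell and 1 rose.

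Other metabolic and stress lists did not pass camera. Among genes of fatty acid synthesis and oxidation, 8 of 24 rose and 5 fell (adjusted p = 0.584). ACAA1, a peroxisomal thiolase, FABP1, the liver fatty acid binding protein, and PLIN2, a lipid droplet coat protein, rose 1.90-fold, 1.66-fold and 1.53-fold, while the elongase ELOVL6 was 2.19-fold lower. With p-values adjusted over the list alone, 8 rose and 7 fell, without siGL replicate 2 the counts were 8 and 3, and with dim genes left out 7 of 19 rose and 8 fell. In cholesterol synthesis and uptake, 2 of 18 rose and 2 fell (adjusted p = 0.917), in all 3 counts. STARD4, a sterol carrier, was 2.84-fold lower and PMVK fell slightly (log2 change -0.26), while INSIG1 and TM7SF2 rose 1.52-fold and 1.39-fold. PMVK lost its call in 5 of the 6 fits that left out 1 array, with a replicate block (limma adjusted p = 0.0780), under housekeeping centring (adjusted p = 0.0890) and with the most variable probe set of each gene (adjusted p = 0.0609). In the unfolded protein and amino acid stress response, 5 of 29 rose and 5 fell (adjusted p = 0.219). PHGDH, of serine synthesis, and ASNS, of asparagine synthesis, rose 1.41-fold and 1.31-fold, and CEBPB and the chaperone DNAJB11 were 1.53-fold and 1.40-fold lower. ASNS lost its call when averaged with its second, very dim probe set (log2 change 0.17 against 0.39; adjusted p = 0.0861), and PHGDH lost its call with a plain t statistic (adjusted p = 0.0647). Adjusted over the list alone, 10 rose and 5 fell, without siGL replicate 2 the counts were 6 and 4, and with dim genes left out 10 of 28 rose and 4 fell.

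The interferon response list had 5 of 31 genes higher and 2 lower. Its median was -0.04, its mean 0.04 and camera pointed up (adjusted p = 0.754). The RNA sensor gene IFIH1 rose from a dim level (2.89 ± 0.38 to 3.79 ± 0.21), IFIT1 rose 1.69-fold and IFIT5 1.43-fold, and ISG20 was 1.34-fold lower. IFIH1 lost its call without siWT replicate 3 and with a plain t statistic, and IFIT5 with its probe sets averaged (log2 change 0.28; adjusted p = 0.0549). When adjusted over the list alone, 6 rose and 2 fell, and without siGL replicate 2 the counts were 4 and 3. In the RNA interference and microRNA machinery, 3 of 11 rose and 0 fell in limma (4 and 0 at an unadjusted p under 0.05; camera adjusted p = 0.102, or 0.334 with an estimated correlation). Without siGL replicate 2 the set passed camera with the preset correlation (adjusted p = 0.0432) but not with an estimated one (adjusted p = 0.359). TNRC6A, XPO5 and TNRC6B rose 1.43-fold, 1.31-fold and 1.28-fold. For TNRC6A this was its brightest probe set, while its other 5 did not pass, and the mean of all of them lost the call (log2 change 0.15 against 0.51; adjusted p = 0.135). TNRC6B lost its call in 4 of the 6 fits that left out 1 array, siGL replicate 2 among them, with its probe sets averaged (log2 change 0.18; adjusted p = 0.139), with the most variable probe set, under housekeeping centring and cyclic loess, and with a plain t statistic. The counts were 3 and 0 both adjusted over the list alone and without that array. Of 26 epithelial and mesenchymal markers, 3 rose and 3 fell (camera adjusted p = 0.896). N-cadherin (CDH2) rose 1.51-fold and occludin (OCLN) 1.41-fold, and the transcription factors SNAI1 and TWIST2 were 1.39-fold and 1.37-fold lower. SNAI1 lost its call in 4 of the 6 fits that left out 1 array, siGL replicate 2 among them, and with a plain t statistic. TWIST2 lost it without siWT replicate 3, with a plain t statistic, with its probe sets averaged (log2 change -0.32) and with the most variable one (-0.19). The counts were the same adjusted over the list alone, 3 higher and 1 lower without siGL replicate 2, and 5 higher and 3 lower of 12 with dim genes left out.

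Markers of cell types that a pure culture lacks were mostly dim. Of 14 leukocyte markers, 1 had a mean of at least 5, and 3 fell with 0 rising in limma (4 and 0 at an unadjusted p under 0.05; camera adjusted p = 0.179). These were lysozyme (LYZ), 1.54-fold lower, and the dim CD2 and CD4, with log2 changes of -0.49 and -0.27. CD4 lost its call in 5 of the 6 fits that left out 1 array, with a replicate block (limma adjusted p = 0.109) and under all 3 normalisations. Its call was also lost with a trended and robust prior, with a plain t statistic, with its probe sets averaged (log2 change -0.13) and with the most variable probe set of each gene. LYZ lost its call with its most variable probe set (log2 change -0.47; adjusted p = 0.139). With p-values adjusted over the list alone, 4 fell and 0 rose, and without siGL replicate 2 the counts were 3 and 0. Of 16 endothelial and fibroblast markers, 2 had a mean of at least 5 and 0 passed in limma in any of the 3 counts (1 at an unadjusted p under 0.05; camera adjusted p = 0.448). The smallest p was that of PDGFRB, with a log2 change of -0.25 (unadjusted p = 0.0102; limma adjusted p = 0.0583), which passed in 6 alternatives (adjusted p from 0.0133 to 0.0490).

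Some members named above kept their call but changed by over 1.5 times when all probe sets of a gene were averaged. The log2 changes were then smaller for TBX3 (-0.30), GOLM1 (-0.42), GPC3 (0.35), SPP1 (-0.33), BCL2L2 (-0.52), BCL2L11 (0.28), CXCL5 (-0.62), IFIH1 (0.29), CCNE1 (-0.39), ETV5 (-0.89), PLIN2 (0.32), ANKRD37 (-0.75) and SMAD3 (-0.55), and larger for BID (0.65) and RRM2 (-0.74). With the most variable probe set they were larger for BID (1.004), RRM2 (-1.07) and ZMAT3 (-1.32).

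In all, 5 of the 22 lists passed camera with its preset correlation, 0 passed with an estimated correlation (3 at an unadjusted p under 0.05) and 12 passed fry, which tests whether a list's genes move on balance in one direction without comparing them with other genes. The camera calls held under the preset correlation of 0.01 and not under an estimated one, where the degrees of freedom are also fewer. Their loss therefore does not by itself show that correlation between genes undoes them. Estimates for these 5 lists ran from 0.017 for hepatocyte transcription factors to 0.162 for G2 and mitosis. For liver metabolic enzymes the estimate was 0.005, below the preset, and their unadjusted camera p still rose from 0.0188 to 0.0671. A higher correlation therefore does not account for every rise in p. With an estimated correlation, camera also uses the few residual degrees of freedom of the fit, which raises p even at an equal correlation. How much of each rise came from either source was not separated here.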

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

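The test of RNA degradation was chosen only after the result it measures was seen. The others in this part were written down before theirs.

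Probe sets without a single gene symbol, which the comparison of genes does not use, also differed between the groups. Of 13522 such probe sets, 621 passed in limma, 353 higher and 268 lower in siWT. This is 4.60% of them, against 10.2% of the probe sets with a single symbol. They are not named here.

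The rise of the plasma protein list was weighed first. Leaving out siGL replicate 2 kept 0.963 of the list's mean shift, so that array alone does not account for it. The smallest shift over quantile, cyclic loess and housekeeping normalisation was 0.959 of the original, so further normalisation did not remove the shift. The authors had already normalised the deposited values between arrays, so these alternatives cannot show what that earlier step did. Among the 23 members with a mean of at least 6 the median shift was 0.37 and 16 passed as higher, so noise near the floor does not account for the shift either. Off-target effects of the siRNA duplexes cannot be told apart from loss of WT1, since 1 arm of WT1 duplexes was analysed and no arm with a single duplex, and a difference in RNA quality stays open too, as the ACTB 3' minus 5' difference and 2 of the 3 control probe sets for 28S ribosomal RNA were higher in siWT once siGL replicate 2 was left out. A rise of plasma protein genes after loss of WT1 therefore stays a hypothesis that needs separate duplexes.

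The other pattern weighed here is the control array siGL replicate 2, with its high ribosomal RNA control signals. Its ACTB 3' minus 5' difference exceeded the highest of the other 5 arrays by 0.293, as RNA degradation would give, so more degraded RNA on that array is a candidate explanation. Over genes with a mean of at least 6, its SD from the other siGL arrays was 1.26 times the highest such value of the other 5 arrays, which leaves open how far the rest of the array is affected. No biological explanation was tested, since the labels set this array apart in no way.

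For the 3219 genes and the 4811 probe sets past the threshold, the 6 arrays can be split into 10 pairs of equal groups. In each case 1 of the 10 splits, the real one, gave as many calls, and the highest count of the other splits was 0 in limma. With 10 splits no share under 0.05 can be reached. Every other split mixes siGL and siWT arrays within each group. A difference between siGL and siWT then widens the spread within groups, so 0 calls there do not show what chance alone would give.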

How the results depend on the processing

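The list counts without siGL replicate 2 and the estimated correlation without it were chosen after seeing the data, and all other alternatives before. WT1 stayed lower and past the threshold in all its alternatives, with log2 changes from -1.32 to -1.19. The count of genes past the threshold stayed within 1.5 times of 3219 except under housekeeping centring (1904, with 897 higher and 1007 lower), a test against a fold of 1.2 (644, with 273 higher and 371 lower, a stricter hypothesis by construction) and with a siWT array left out. Leaving out 1 array gave 1854 to 2804 genes, 914 to 1486 higher and 940 to 1417 lower, with 1896, 2102 and 1854 genes without siWT replicates 1, 2 and 3, where fewer samples were fitted. Called genes shared with the original fit kept their sign in every alternative except with the highest variance probe set, where 2308 of 2333 did. Against 4811 probe sets past the threshold, 7279 passed with a trended and robust prior, and leaving out 1 array gave 2383 to 4464, with 3089 without siGL replicate 1 and 2383, 2864 and 2463 without siWT replicates 1, 2 and 3. Apart from the effect of fewer samples, the cause of these moves was not tested. Of the 22 lists, 5 passed camera, 0 with an estimated correlation and 12 with fry. Hepatocyte transcription factors lost the call under both dim filters, with a mean log2 change of 0.20 and 0.17 against 0.16 over all members, and liver metabolic enzymes gained it in 7 alternatives, with adjusted p from 0.0139 to 0.0399, among them all 3 normalisations. NF-kappaB targets gained it above the median gene (0.0437) and the RNA interference list without siGL replicate 2 (0.0432), while with an estimated correlation over all arrays the adjusted p of these 3 lists was 0.295, 0.334 and 0.334. For the 100 other named genes, 1682 values kept direction and side of the threshold, 96 lost the call, 6 gained it and 0 reversed, with 27 of the losses in the stricter test against a fold of 1.2. The numbers 1 to 3 did not pair the samples, with correlations of deviations of -0.04, -0.08 and -0.01 for the same number and 0 of 6 samples correlating best with their own number. A replicate block gave 2363 genes, 1170 higher and 1193 lower, 3656 probe sets, 5 lists and a WT1 change of -1.24. The ACTB 3' minus 5' difference between groups, 0.004 over all arrays, ran from -0.096 to 0.197 when 1 array was left out, with -0.096, 0.197 and -0.090 without siGL replicates 1, 2 and 3, and the highest value comes from leaving out the array that stands apart. Dim genes passed less often, as 720 of the 3219 genes had a mean under 5, against 10850 of the 19775 tested. Low signal may limit these genes, which was not tested.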

Other observations

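The immediate early, ERK feedback, further ERK target and CREB target lists were chosen only after the strongest changes had been seen, and the tests on single dishes and on ERK output were written after values they use were seen. The test on CREB output was written before its values were seen.

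Of 29 measured immediate early genes, which growth factors and stress induce within minutes, 16 fell in siWT and 13 did not pass. The orphan receptor genes NR4A2 and NR4A1 were 2.93-fold and 2.62-fold lower, the kinase SGK1 2.43-fold lower, IER2 2.13-fold lower, and DUSP1, a phosphatase of MAP kinases, 1.85-fold lower. NR4A2 went from 7.17 ± 0.04 to 5.62 ± 0.05 (SD, n = 3 each; limma adjusted p = 1.39e-05). The members JUN, ATF3, KLF6, KLF10, MYC and MCL1 did not pass, with log2 changes of 0.23, 0.18, 0.04, 0.03, -0.04 and -0.07. The list had a mean log2 change of -0.58, but it was drawn up after IER3 and EGR1 had been seen to fall, so it is not independent evidence of a direction. Of 17 measured ERK feedback genes, 12 of which the ERBB list also holds, 11 fell and 1, PHLDA1, rose. Those 12 had been seen before this list was drawn up, so its count is not independent evidence either, and no p-value is given for these 2 lists. Of the members outside the ERBB list, ETV1 was 1.75-fold lower with a wide error (log2 change -0.81, SE 0.22), while CCND1, SPRED3, LZTS1 and IL11 did not pass (0.04, 0.00, 0.01 and -0.14).

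Several explanations were weighed for the lower immediate early and ERK feedback genes. The widest range of the immediate early list's mean within a group was 0.0635 of the difference between the groups, so no single array carried the difference. The list was drawn up after members with groups that did not overlap had been seen, which favours a small value. This test therefore cannot decide whether single dishes were handled differently at harvest. Handling or RNA quality that differed for a whole group, off-target effects of the duplexes and loss of WT1 itself were not tested apart and stay open. Lower ERK pathway output may contribute, as 14 further ERK targets outside the fixed lists had a median log2 change of -0.11. Of these, SLC20A1, EPHA2, POLR3G and UPP1 fell and 10 did not pass (camera adjusted p = 0.0188, but adjusted p = 0.162 with an estimated correlation, over the 3 lists tested together). Several of the 10 were dim, among them EMP1, TFPI2 and MMP1 with means of 1.91, 1.65 and 1.49. The median therefore rests partly on genes near the floor. Lower CREB output was left open by a median of -0.0402 over 19 CREB targets, of which 3 rose and GEM fell. Camera, in limma, gave this list an adjusted p of 0.932 over the same 3 lists.

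Apart from the fixed lists, 134 families of genes that share a symbol stem were tested with camera among genes with a mean of at least 5, each with at least 8 such members, so families of mostly dim genes were not tested, and 0 passed after adjustment (11 at an unadjusted p under 0.05, and 0 after adjustment with an estimated correlation). The smallest p was that of the proteasome subunit stem PSMB, with 4 of 8 genes lower and 0 higher in limma. After adjustment over the 134 stems its camera p was 0.282. Of the 756 genes with at least 2 called probe sets, 30 had probe sets called in opposite directions, among them LAMP2, with log2 changes of -0.43 and 0.85, and NUP98, with -0.43 and 1.26.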
